A study of Homo sapiens with 18 samples.

How the data were processed

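RNA was measured by poly(A)-selected RNA sequencing in 18 libraries from the human myeloma cell lines KMS12-BM and JJN3, treated for 24 h with amiloride or TG003, or labelled as untreated (DMSO) with no duration given, with 3 libraries in each of the 6 groups. Per the labels, amiloride was given at 0.1 mM to KMS12-BM and at 0.4 mM to JJN3, and TG003 at 0.4 mM to both. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between samples.

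Per the submitters' processing notes, adapters were removed with cutadapt 1.4, reads were aligned to hg19 with TopHat2 2.0.11, reads were counted per gene with HTSeq 0.6.1p1, and expression was compared with DESeq2 1.12.4. The alignment options, the gene annotation used for counting and the strandedness setting are not given in the sources used here. The deposited count files hold 1 whole-number read count per Ensembl gene and library, for 57905 genes in each of the 18 files, followed by the counts of reads that HTSeq gave to no gene. The 3 deposited tables of normalized signal hold values that the authors made by dividing each count by a size factor of its library. For counts of at least 500, these values were within 0.496% of the count divided by 1 factor per library. They were used only for that check, and no unit other than counts entered a test. Reads as sequenced were not used here.

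Gene symbols, gene classes and coordinates (GRCh37/hg19) were joined by Ensembl identifier to the annotation at hand, which matched 55538 identifiers and gave a symbol to 43521. The share of HTSeq's records outside genes was computed per library. These are reads that fell in no gene, in more than 1 gene, or at more than 1 place in the genome.

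The main analysis used edgeR 4.0.16 in R 4.3.3 on the counts. Each line was fitted alone with its 9 libraries. Genes were kept by filterByExpr (a minimum count of 10, and 15 in total), libraries were scaled by the trimmed mean of M-values (TMM), and group means were compared by quasi-likelihood F tests with robust dispersion. The difference between the lines in the response to each drug was the interaction term of 1 fit to all 18 libraries. A gene was called higher or lower at a Benjamini-Hochberg adjusted p under 0.05, in 6 pairwise comparisons and 2 interactions. All adjusted p of single genes given below are from edgeR unless another tool is named. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic, which is an approximation, and it is written after ± unless SD is stated. Levels are in CPM, counts relative to the scaled library size, with the SD over 3 libraries. Counts are of reads, and reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. Where a group had a count of 0, the fold is a lower bound against a floor of 3 counts over the group, because a fitted fold change of such a gene depends on the prior count and is no bound.

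The 32 gene lists, the genes named in every comparison and the rule for the other named genes were fixed before the data were examined, as were the tests and the first set of alternatives. Named were the 5 largest rises and the 5 largest falls among genes with an adjusted p under 0.05, a symbol, a mean of at least 5 CPM over the 9 libraries of the line and CPM ranges that did not overlap between the groups. With 3 against 3 libraries, chance gives ranges that do not overlap in 10% of genes. For interactions the range condition was left out. For each list called by camera, the 3 members with the smallest adjusted p in the direction of the list were added. Some of the genes chosen by these rules are not reported here.

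Lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01 between genes, which compares the genes of a list with all other tested genes, and p was adjusted over the 32 lists of a comparison. Of the 73 calls among 256 list tests, 2 held when the correlation was estimated per list: cholesterol biosynthesis with amiloride in JJN3 (adjusted p = 0.00341) and MYC targets and nucleolar genes in the TG003 interaction (adjusted p = 0.00868). The rotation test fry asks whether the genes of a list move on balance 1 way and does not compare them with other genes. Counts of members are given over all tested genes and, where they differ, adjusted over the list alone.

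Alternatives fixed at that time were DESeq2's median-of-ratios factors and upper-quartile factors in place of TMM, removal of the 10 most abundant genes of each line, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0 and limma voom in place of edgeR's test, the library-number set as a replicate block, a fit of the compared groups alone, and each library left out in turn. For lists they were an estimated correlation, fry and a test on ranks. For the agreement between responses they were Spearman's rho and genes with a mean of at least 10 CPM.

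Other alternatives were chosen after seeing the data. Processed pseudogenes were matched to coding genes by aligning transcripts with minimap2 2.31, which gave 5870 of 10124 pseudogenes a parent among 2123 coding genes. In 1 alternative the counts of each pseudogene were added to its parent. In another, only the 14796 of 19404 coding genes without a near copy were fitted, that is, without a processed pseudogene or another transcript of at least 90% identity over 100 bases. In 2 more, a smooth trend over mean exon length (with the same genes) or over the GC content of the longest transcript (all genes) was removed from each library as an offset, by local regression with a span of 0.3. In the comparisons with TG003, the 10 largest rises and falls among genes without a near copy were taken as well, under the conditions above.

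The depth was 23707695 to 50570234 reads in genes per library. Few gene changes were simulated, with the spread of these libraries. There edgeR recovered 72.1% and 71.4% of 2-fold changes in KMS12-BM and JJN3, and 41.9% in the interaction, with 14, 13 and 2 false calls. Without any change, calls numbered 2, 1 and 0. A simulated 0.5 log2 shift of the core spliceosome list was called in all 3 designs, with 0, 1 and 0 of 31 other lists. False list calls in correlated genes stay open. Figures used matplotlib 3.10.9 in Python 3.11.15. Exons and splicing were not analysed, as counts are per gene.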

Results

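The data are gene-level read counts from 18 poly(A)-selected RNA-seq libraries of the human myeloma cell lines KMS12-BM and JJN3. Cells were treated for 24 h with amiloride, a diuretic that blocks epithelial sodium channels and sodium-proton exchangers, or with TG003, an inhibitor of the CLK kinases that phosphorylate SR splicing proteins. The controls were labelled as untreated (DMSO), without a duration, and were taken as solvent controls. There were 3 libraries in each of the 6 groups. The dose of amiloride was 0.1 mM in KMS12-BM and 0.4 mM in JJN3, and that of TG003 was 0.4 mM in both lines. Reads in genes ranged from 29794926 to 50570234 per library in KMS12-BM and from 23707695 to 44601334 in JJN3. Between 18943 and 21893 genes had at least 1 read in a library, and the 10 most abundant genes held 2.873% to 5.814% of the reads.

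The libraries differed in composition by drug. Mitochondrially encoded genes held 4.062% ± 0.192 of the reads (SD, n = 3) in KMS12-BM with DMSO, 0.3585% ± 0.0917 with amiloride and 3.964% ± 0.493 with TG003. The corresponding shares in JJN3 were 2.294% ± 0.282, 0.8307% ± 0.178 and 2.311% ± 0.49. Processed pseudogenes, which are genomic copies of spliced messenger RNAs, held 4.488% to 5.615% of the reads in the 12 DMSO and amiloride libraries and 0.1062% to 0.13% in the 6 TG003 libraries. Reads aligned to more than 1 place in the genome made up 13.26% to 17.44% in the former and 7.791% to 9.125% in the latter. All 6 TG003 libraries thus stood apart from the other 12 in how reads were placed, and every comparison between TG003 and another group carries that difference.

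Amiloride against DMSO in KMS12-BM asks what the drug changed in this line at 0.1 mM. The messenger RNAs of the mitochondrial genome fell most. All 12 messengers encoded on its heavy strand were lower, with a median log2 fold change of -5.22 and a range of -6.54 to -3.78. MT-CO1, a catalytic subunit of cytochrome c oxidase (chromosome M, 5904 to 7445), went from 6185 CPM to 66.3 CPM (log2 -6.54 ± 0.31, adjusted p = 1.33e-07). MT-ND3 (-6.54 ± 0.28), MT-CO3 (-6.36 ± 0.23) and MT-CO2 (-6.23 ± 0.29) were the next. The other 3 genes of the list rose: MT-ND6, the messenger of the light strand, by 2.70 ± 0.35, and the ribosomal RNAs MT-RNR1 by 1.55 ± 0.12 and MT-RNR2 by 0.99 ± 0.16. As a list, the 15 mitochondrially encoded genes were lower than other genes (3 higher, 12 lower, median -4.56, camera adjusted p = 3.68e-12), with adjusted p = 0.224 with estimated correlation.

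**Figure D1:**
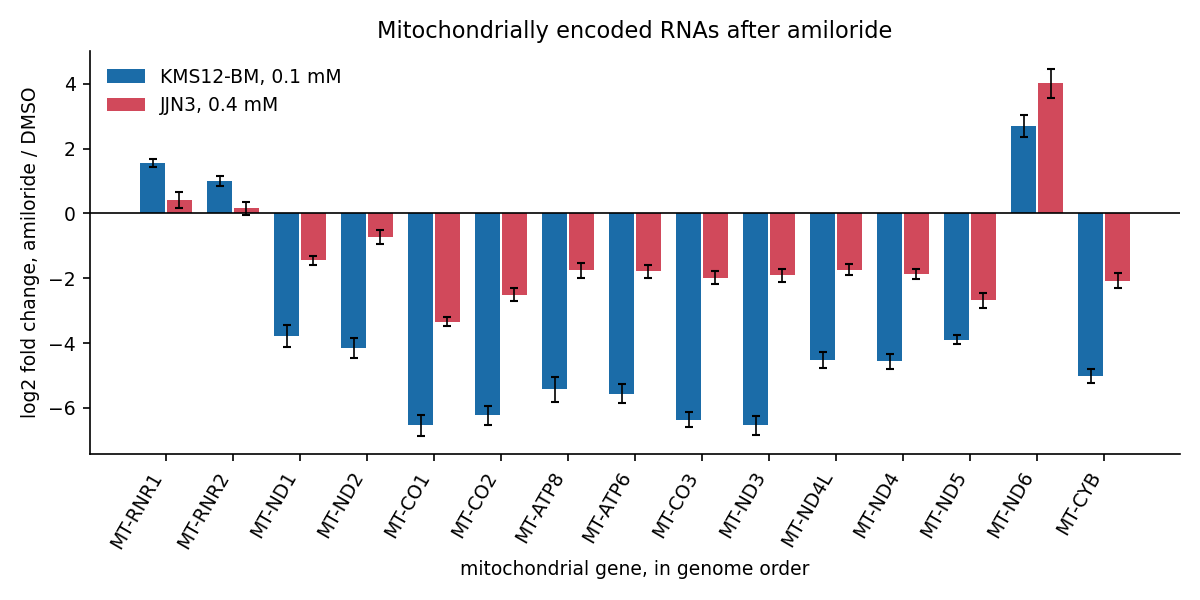
Log2 fold change of amiloride against DMSO (vertical axis) for the 15 mitochondrially encoded genes in their order along the mitochondrial genome (horizontal axis), with 3 libraries per group, bars for the fitted value, whiskers for its standard error and 1 colour per line. The 12 heavy-strand messengers lie between -6.54 and -3.78 in KMS12-BM and between -3.34 and -0.73 in JJN3, while MT-ND6 is at 2.70 and 4.01.

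Outside the mitochondrial genome the largest rises were in NPC1L1, the intestinal cholesterol transporter (chromosome 7, 44552134 to 44580929), which went from 0.162 ± 0.0729 CPM to 21.6 ± 4.68 CPM (SD, log2 7.10 ± 0.28, adjusted p = 1.24e-08), the long noncoding RNA ZNNT1 (6.15 ± 0.33), ZNF512B (4.47 ± 0.16), the histone gene H4C8 (4.46 ± 0.18; chromosome 6, 26277837 to 26285866) and the membrane protease MMP14 (4.26 ± 0.18). The largest fall of a nuclear gene was that of PFKFB4, a regulator of glycolysis (chromosome 3, 48555117 to 48599448), from 23.7 CPM to 0.375 CPM (-5.96 ± 0.28, adjusted p = 3.79e-08).

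Genes of the ATF4 and integrated stress response list rose in KMS12-BM. Of 26 measured, 23 were higher, 0 lower and 3 not called (median 1.14, camera adjusted p = 4.05e-07, and adjusted p = 0.304 with estimated correlation). Adjusted over the list alone, 23 were higher and 1 lower. DDIT3, which encodes the stress factor CHOP (chromosome 12, 57910371 to 57915520), went from 19.2 CPM to 165 CPM (3.11 ± 0.24, adjusted p = 1.98e-06). STC2 rose by 2.38 ± 0.14, the transporter gene SLC3A2 by 2.10 ± 0.13 and ATF3 by 1.70 ± 0.14. ATF4 itself rose by 0.26 ± 0.09. Of 30 measured genes of ER chaperones and ER-associated degradation, 7 were higher and 16 lower (median -0.523, camera adjusted p = 0.0325, 0.224 as adjusted p with estimated correlation), a call lost without amiloride replicate 1 (median -0.511). HSPA5, the main ER chaperone, changed by -2.07 ± 0.12.

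Of 37 G1/S and DNA replication genes, 31 were lower and 1 higher (median -0.979, camera adjusted p = 3.68e-12, and adjusted p = 0.128 with estimated correlation), or 32 lower and 1 higher adjusted over the list alone. Among 37 DNA repair genes 18 were lower and 7 higher (median -0.26, camera adjusted p = 0.0367, adjusted p = 0.391 with estimated correlation). Without amiloride replicate 1 this call was lost (median -0.214), and without DMSO replicate 3 the median was -0.145. Replication-dependent histones, whose messengers normally lack poly(A) tails, were higher in 9 of 11 and lower in 1 (median 2.0, camera adjusted p = 4.5e-06, adjusted p = 0.224 with estimated correlation). Of 24 cholesterol biosynthesis genes 23 were lower and 0 higher (median -1.33, camera adjusted p = 1.2e-10, adjusted p = 0.224 with estimated correlation), among them LSS (-2.32 ± 0.12).

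Metabolic and redox lists also fell. Hypoxia and glycolysis genes were lower in 20 of 29 and higher in 6 (median -0.657, camera adjusted p = 0.00308, adjusted p = 0.224 with estimated correlation), or 21 lower adjusted over the list alone. The aldolase gene ALDOC was at -3.14 ± 0.13 and the pyruvate kinase gene PKM at -1.28 ± 0.07. NRF2 and oxidative stress genes were lower in 15 of 24 and higher in 3 (median -0.696, camera adjusted p = 0.000368, adjusted p = 0.128 with estimated correlation). PIR was at -4.19 ± 0.17. Ion and volume homeostasis genes were lower in 16 of 24 and higher in 7 (median -0.675, camera adjusted p = 0.012, adjusted p = 0.224 with estimated correlation). The volume-sensing kinase gene OXSR1 was at -1.42 ± 0.08. The 16 amiloride-sensitive transport genes were not called as a list (2 higher, 11 lower, median -0.426, adjusted p = 0.133). SCNN1A, the alpha subunit of the epithelial sodium channel, changed by -4.19 ± 0.45 from a level of 1.20 CPM.

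Genes of cell death and of myeloma biology changed in both directions. Apoptosis regulators were higher in 19 of 29 and lower in 6 (median 0.491, camera adjusted p = 0.00135, adjusted p = 0.224 with estimated correlation). They included the proapoptotic BBC3 (1.62 ± 0.18), BCL2L11 (1.25 ± 0.09), HRK (1.29 ± 0.09) and death receptor gene TNFRSF10B (2.17-fold higher), and the antiapoptotic MCL1 (0.81 ± 0.07) and CFLAR (1.17 ± 0.07). NF-kappaB targets were higher in 13 of 20 and lower in 3 (median 0.759, camera adjusted p = 0.00632, adjusted p = 0.257 with estimated correlation). The myeloma oncogene list was higher in 12 of 23 and lower in 4 (median 0.295, or 0.162 without DMSO replicate 2, camera adjusted p = 0.012, adjusted p = 0.224 with estimated correlation). Its 3 leading members were CYLD (1.91 ± 0.08) and RB1 (1.80 ± 0.10), both known as tumour suppressors, and CRBN (1.47 ± 0.10), the target of lenalidomide. MYC, the growth regulator (chromosome 8, 128747680 to 128755197), fell by 1.08 ± 0.13 on the log2 scale (adjusted p = 2.28e-05). The plasma cell factors IRF4 (0.85 ± 0.07) and XBP1 (0.76 ± 0.09) rose, and PRDM1 was at 0.17 ± 0.07 (adjusted p = 0.0592). Of p53 targets MDM2 rose (0.33 ± 0.09) and CDKN1A (0.44 ± 0.29, under 1 CPM, adjusted p = 0.197) was not called. CYP1A1, a target of the aryl hydrocarbon receptor, changed by -1.24 ± 0.09. CCND1 was at 0.06 ± 0.18 (adjusted p = 0.781) and MAF at -0.02 ± 1.08 (adjusted p = 0.99).

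SR protein kinases, which phosphorylate splicing factors, were higher in 8 of 11 and lower in 1 (median 0.543, camera adjusted p = 0.00396, adjusted p = 0.224 with estimated correlation). CLK1 rose by 2.49 ± 0.15, CLK3 by 1.76 ± 0.10, CLK4 by 1.38 ± 0.16 and PRPF4B by 0.83 ± 0.06, while CLK2 was at -0.18 ± 0.09 (adjusted p = 0.0855; called without amiloride replicate 2, -0.2375). Of their substrates, SRSF1 was at 0.10 ± 0.06 (adjusted p = 0.184). SF3B1 of the U2 particle rose by 0.70 ± 0.10. SR proteins (12 higher and 4 lower of 23, median 0.292, adjusted p = 0.0607), the core spliceosome (24 and 11 of 50, 0.154, adjusted p = 0.103) and hnRNP proteins (10 and 6 of 25, 0.0737, adjusted p = 0.501) were not called. The SR protein list was called without amiloride replicate 3 (0.282) and in genes without a near copy (9 higher and 2 lower of 15, 0.493, adjusted p = 0.0208, but 0.328 with estimated correlation and 0.0604 with the exon-length trend removed), and also with DESeq2, with fry, on ranks and without a filter. The core spliceosome was called with fry, without a filter and with a GC trend removed, and hnRNP proteins with fry.

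Further lists without a call in KMS12-BM were p53 targets (11 higher and 10 lower of 26, adjusted p = 0.836), G2/M and mitosis (17 and 5 of 38, 0.356; called without amiloride replicate 1, median 0.318), immediate-early genes (10 and 3 of 28, 0.103), MYC targets and nucleolar genes (8 and 22 of 38, 0.258; 9 and 23 adjusted over the list alone), plasma cell identity (6 and 12 of 27, 0.317), heat shock proteins (6 and 12 of 25, 0.852) and the proteasome (7 and 15 of 36, 0.341; 6 and 15 adjusted over the list alone). The same held for ribosomal proteins (2 and 28 of 69, adjusted p = 0.203, or 2 and 24 adjusted over the list alone), nuclear-encoded oxidative phosphorylation (5 and 13 of 44, 0.336) and markers of other blood and stromal cells (6 and 6 of 13, 0.909). Signs differed within 4 lists. Lysosomal genes (12 and 12 of 39, adjusted p = 0.984) had a median of 0.0546, a mean of -0.0412 and a test direction upward, and polyamine genes (7 and 7 of 21, adjusted p = 0.984) had 0.0264, -0.0769 and downward. For aryl hydrocarbon receptor targets (3 and 3 of 7, adjusted p = 0.92, or 3 and 4 adjusted over the list alone) the median was -0.238, the mean 0.026 and the test upward. For interferon genes (7 and 7 of 17, adjusted p = 0.609) they were -0.072, 0.419 and upward.

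In total edgeR called 10835 of 15765 genes (68.7%), with 5281 higher and 5554 lower, and 1893 and 2780 of these changed at least 2-fold. The change followed the GC content of the transcripts: over 8842 coding genes without a near copy, Spearman's rho was -0.387 across genes, which are not independent replicates, and the median log2 was 0.388 in genes with at most 42.5% GC and -0.634 in those with at least 58.4%. With a GC trend removed per library, the core spliceosome (median 0.257, adjusted p = 0.015) and immediate-early genes (0.442, 0.0018) were called as higher, MDM2 (-0.04) and SRSF1 (-0.28) turned direction, and the 14 list calls of this comparison stood. The calls for ER chaperones and ER-associated degradation, amiloride against DMSO in KMS12-BM, and for DNA repair and Fanconi anaemia, amiloride against DMSO in KMS12-BM, were lost with a filter of 1 CPM and in genes without a near copy (adjusted p of 0.00374 to 0.224 and 0.000535 to 0.391 over all alternatives but fry), and the latter also with limma voom, with the library-number set as a block, in a fit of the compared groups alone and with pseudogene counts summed into parents.

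Amiloride against DMSO in JJN3 asks the same at 0.4 mM in the other line. Hypoxia and glycolysis genes fell together, with 31 of 33 lower and 1 higher (median -0.969, camera adjusted p = 1.66e-29, and adjusted p = 0.0887 with estimated correlation). PFKFB4 went from 126 CPM to 12.1 CPM (log2 -3.38 ± 0.23, adjusted p = 1.17e-05, n = 3 per group). PDK1, which inhibits pyruvate dehydrogenase, changed by -2.19 ± 0.10, ALDOC by -2.17 ± 0.11 and the mitophagy receptor gene BNIP3L by -1.34 ± 0.07. Cholesterol biosynthesis genes were lower in 21 of 24 and higher in 1 (median -0.656, camera adjusted p = 9.52e-15, a call that held with estimated correlation).

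The 12 heavy-strand mitochondrial messengers were all lower in JJN3 as well, with a median of -1.88 and a range of -3.34 to -0.727. MT-CO1 went from 5549 CPM to 547 CPM (-3.34 ± 0.14). MT-ND6 (chromosome M, 14149 to 14673, minus strand) rose from 23.5 CPM to 380 CPM (4.01 ± 0.45, adjusted p = 0.000473), which was the largest rise in this comparison. MT-RNR1 was at 0.42 ± 0.24 (adjusted p = 0.2) and MT-RNR2 at 0.15 ± 0.21 (adjusted p = 0.583). The list of 15 was called as lower (1 higher, 12 lower, median -1.79, camera adjusted p = 1.86e-14, adjusted p = 0.346 with estimated correlation). Other large rises were in the nucleic acid sensor ZBP1 (2.31 ± 0.15), LINC00899 (2.14 ± 0.13) and ZNNT1 (1.89 ± 0.19). Large falls were also in the pseudogenes MTCO1P12 (-3.02 ± 0.22), a nuclear copy of MT-CO1, and RPS4XP3 (-2.59 ± 0.22).

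ATF4 and integrated stress response genes were lower in 16 of 27 and higher in 1 (median -0.448, camera adjusted p = 2.93e-05, adjusted p = 0.346 with estimated correlation), or 17 lower adjusted over the list alone. The folate enzyme gene ALDH1L2 changed by -1.69 ± 0.14, CTH by -1.38 ± 0.13 and ATF3 by -0.40 ± 0.13, and the 1 higher member was ATF5 (1.60 ± 0.14). The call for ATF3 was lost without DMSO replicate 3 (-0.331) or amiloride replicate 3 (-0.271). DDIT3 was at 0.26 ± 0.14 (adjusted p = 0.161). ER chaperones were lower in 19 of 30 and higher in 2 (median -0.29, camera adjusted p = 0.00133, adjusted p = 0.186 with estimated correlation). The disulfide isomerase gene P4HB was at -0.89 ± 0.10. Plasma cell identity genes were lower in 11 of 28 and higher in 1 (median -0.342, camera adjusted p = 0.0284, adjusted p = 0.414 with estimated correlation), a call lost without DMSO replicate 1 (-0.271) or amiloride replicate 3 (-0.249).

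G2/M and mitosis genes were lower in 28 of 38 and higher in 0 (median -0.426, camera adjusted p = 9.68e-07, adjusted p = 0.414 with estimated correlation), or 29 lower adjusted over the list alone. KIF20A was lower by a factor of 1.99. G1/S and DNA replication genes were lower in 20 of 37 and higher in 1 (median -0.346, camera adjusted p = 0.000195, adjusted p = 0.529 with estimated correlation), or 23 lower adjusted over the list alone. DNA repair genes were lower in 19 of 37 and higher in 3 (median -0.275, camera adjusted p = 0.00388, adjusted p = 0.529 with estimated correlation). Replication-dependent histones were higher in 6 of 13 and lower in 0 (median 0.421, camera adjusted p = 0.00116, adjusted p = 0.414 with estimated correlation). Without amiloride replicate 3 the medians were -0.224 for G1/S and -0.177 for DNA repair, and without amiloride replicate 2 that of histones was 0.663.

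The core spliceosome was higher in 26 of 50 and lower in 1 (median 0.237, camera adjusted p = 2.9e-06, adjusted p = 0.388 with estimated correlation), or 27 higher adjusted over the list alone. PRPF3 was at 0.79 ± 0.07. SR proteins were higher in 9 of 23 and lower in 1 (median 0.119, camera adjusted p = 0.00869, adjusted p = 0.43 with estimated correlation). LUC7L was at 0.98 ± 0.09. The hnRNP list was higher in 12 of 25 and lower in 2 (median 0.188, camera adjusted p = 0.00869, adjusted p = 0.414 with estimated correlation), or 13 higher adjusted over the list alone. HNRNPUL2 was at 0.60 ± 0.06. SR protein kinases were higher in 5 of 11 and lower in 1 (median 0.195, camera adjusted p = 0.0108, adjusted p = 0.414 with estimated correlation). CLK1 was at 1.11 ± 0.14 and PRPF4B at 0.75 ± 0.07. The median of these kinases was 0.0867 without DMSO replicate 1, 0.356 without amiloride replicate 2 and 0.104 without amiloride replicate 3, and that of SR proteins 0.0611 without amiloride replicate 2. SF3B1 rose by 0.45 ± 0.07. CLK2 (-0.06 ± 0.11, adjusted p = 0.659), CLK4 (0.00 ± 0.12, adjusted p = 0.997) and SRSF1 (0.06 ± 0.09, adjusted p = 0.63) were not called.

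MYC targets and nucleolar genes were higher in 22 of 38 and lower in 4 (median 0.254, camera adjusted p = 0.000167, adjusted p = 0.388 with estimated correlation), or 22 and 6 adjusted over the list alone. MYC itself fell by 0.63 ± 0.07 on the log2 scale (adjusted p = 3.8e-05). Proteasome genes were higher in 13 of 36 and lower in 2 (median 0.192, camera adjusted p = 0.000832, adjusted p = 0.414 with estimated correlation). Heat shock proteins were higher in 10 of 24 and lower in 3 (median 0.119, camera adjusted p = 0.0321, adjusted p = 0.446 with estimated correlation). The heat shock call was lost without DMSO replicate 3 (0.125). Without DMSO replicate 1 its median was 0.185 and that of the proteasome 0.302. Ribosomal protein genes were lower in 45 of 69 and higher in 1 (median -0.291, camera adjusted p = 9.68e-07, adjusted p = 0.388 with estimated correlation), or 47 lower adjusted over the list alone.

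Of single genes, CYP1A1, a target of the aryl hydrocarbon receptor, rose by 1.81 ± 0.20. The proapoptotic BBC3 (-0.88 ± 0.20) and PMAIP1 (-0.53 ± 0.16) fell, MCL1 rose (0.43 ± 0.09), and BCL2L11 was at -0.12 ± 0.08 (adjusted p = 0.227). CDKN1A (-0.69 ± 0.16), MDM2 (-0.31 ± 0.07), XBP1 (-0.34 ± 0.09) and MAF (-0.35 ± 0.12) fell. IRF4 (-0.13 ± 0.12, adjusted p = 0.417), PRDM1 (-0.35 ± 0.14, adjusted p = 0.0712) and CCND1 (0.48 ± 0.20, adjusted p = 0.0661) were not called. PMAIP1 was lost without DMSO replicate 2 or 3 or amiloride replicate 1 or 3 (-0.4832 to -0.4414), and MAF without DMSO replicate 3 or amiloride replicate 1 or 3 (-0.3663 to -0.2098). PRDM1 was called without amiloride replicate 1 (-0.492). PMAIP1 was too low to be tested in KMS12-BM alone and SCNN1A in JJN3 alone.

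Lists without a call in JJN3 were NRF2 (1 higher and 9 lower of 25, adjusted p = 0.0547), NF-kappaB targets (3 and 8 of 21, 0.089), p53 targets (6 and 9 of 28, 0.674; 6 and 10 adjusted over the list alone), lysosome (3 and 11 of 39, 0.906), apoptosis regulators (10 and 6 of 30, 0.289; 11 and 7 adjusted over the list alone), amiloride-sensitive transport (2 and 3 of 13, 0.515), ion and volume homeostasis (4 and 8 of 27, 0.744), aryl hydrocarbon receptor targets (4 and 3 of 10, 0.256), interferon response (6 and 3 of 26, 0.477), immediate-early genes (7 and 5 of 30, 0.256) and oxidative phosphorylation (4 and 7 of 44, 0.507). Myeloma oncogenes (5 and 7 of 27, adjusted p = 0.812) had a median of 0.0324, a mean of -0.0733 and an upward test direction. For markers of other cells (3 and 1 of 11, adjusted p = 0.515) these were -0.0275, 0.241 and upward, and for polyamine genes (4 and 5 of 20, adjusted p = 1, or 4 and 6 adjusted over the list alone) -0.00367, -0.0722 and upward. Calls were gained for NRF2 without DMSO replicate 3 (-0.22) or amiloride replicate 2 (-0.204), for NF-kappaB targets without DMSO replicate 1 (-0.151) or 3 (-0.0961) and for immediate-early genes without DMSO replicate 3 (0.254).

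In JJN3 edgeR called 6842 of 15704 genes (43.6%), with 3092 higher and 3750 lower, and 437 and 684 changed at least 2-fold. The GC trend was weaker here (rho -0.143 across genes, medians of 0.033 up to 42.2% GC and -0.137 from 57.8%). The call for heat shock proteins, amiloride against DMSO in JJN3, was lost without the 10 most abundant genes, with the library-number set as a block, in genes without a near copy and with pseudogene counts summed into parents (adjusted p of 0.00336 to 0.446 over its alternatives). That for SR protein kinases was lost in genes without a near copy (median 0.267, adjusted p = 0.0611).

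**Figure D2:**
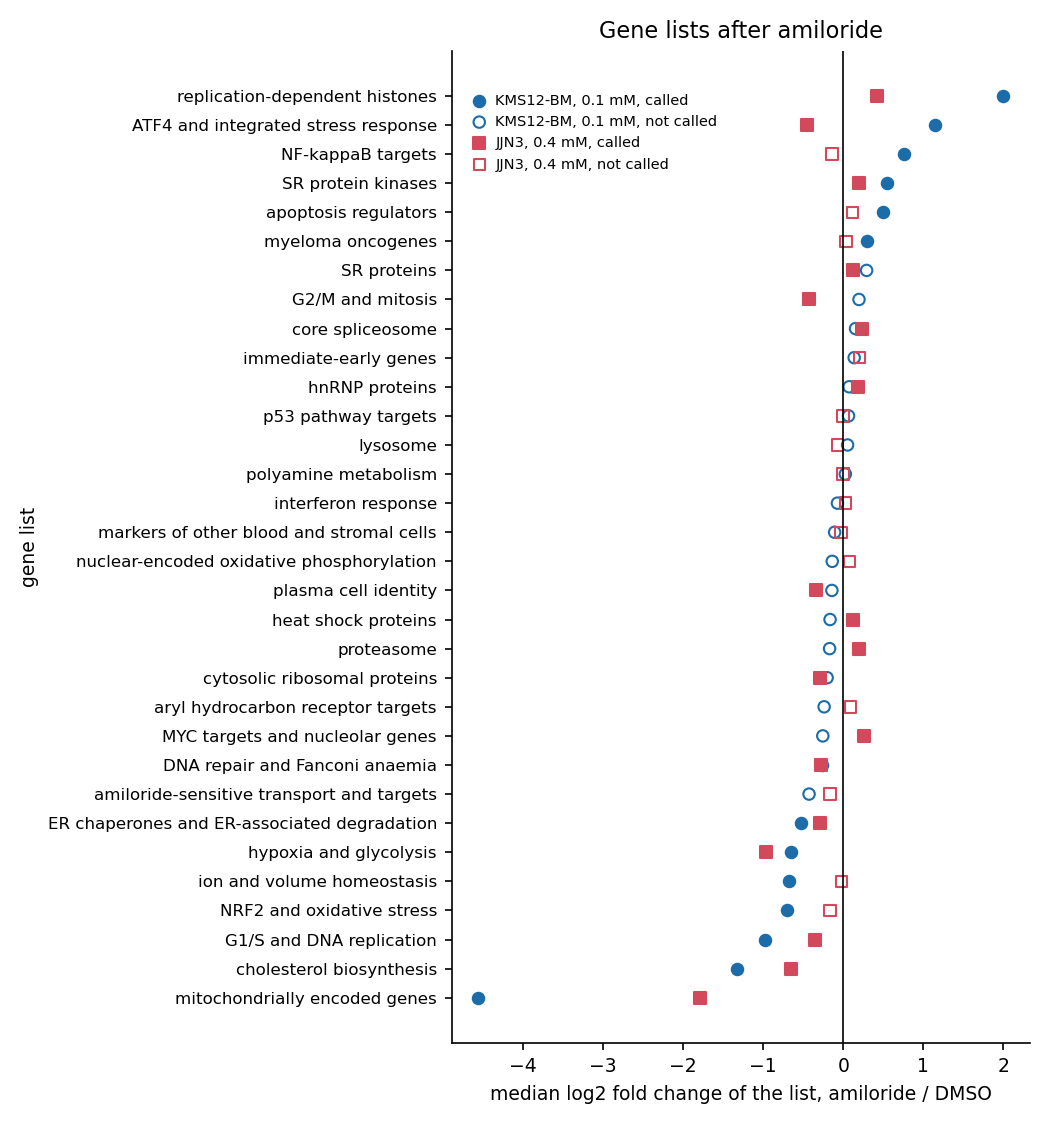
Median log2 fold change of amiloride against DMSO for the fixed gene lists in KMS12-BM (at 0.1 mM) and in JJN3 (at 0.4 mM), with 3 libraries per group and each symbol the median over the measured members of a list (circles KMS12-BM, squares JJN3, filled where camera made a call). Mitochondrially encoded genes lie at -4.56 and -1.79, cholesterol biosynthesis at -1.33 and -0.656, and ATF4 and integrated stress response genes on opposite sides at 1.14 and -0.448.

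The difference between the lines in the response to amiloride was tested as an interaction, in which a positive log2 value means a higher fold change in KMS12-BM than in JJN3. Both dose and line differ in this contrast. The ATF4 and integrated stress response list differed most in its test: 25 of 28 genes had a higher fold change in KMS12-BM and 0 a lower one (median 1.72, camera adjusted p = 6.09e-19, adjusted p = 0.153 with estimated correlation). STC2 was at 2.93 ± 0.16, SLC3A2 at 2.14 ± 0.15 and DDIT3 at 2.84 ± 0.31. All 12 heavy-strand mitochondrial messengers fell further in KMS12-BM (median -3.32, -4.63 to -1.22). The list of 15 was called (2 higher, 12 lower, median -2.95, camera adjusted p = 5.04e-11, adjusted p = 0.243 with estimated correlation), or 13 lower adjusted over the list alone. MT-ND6 was at -1.31 ± 0.57 (adjusted p = 0.0833).

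**Figure D3:**
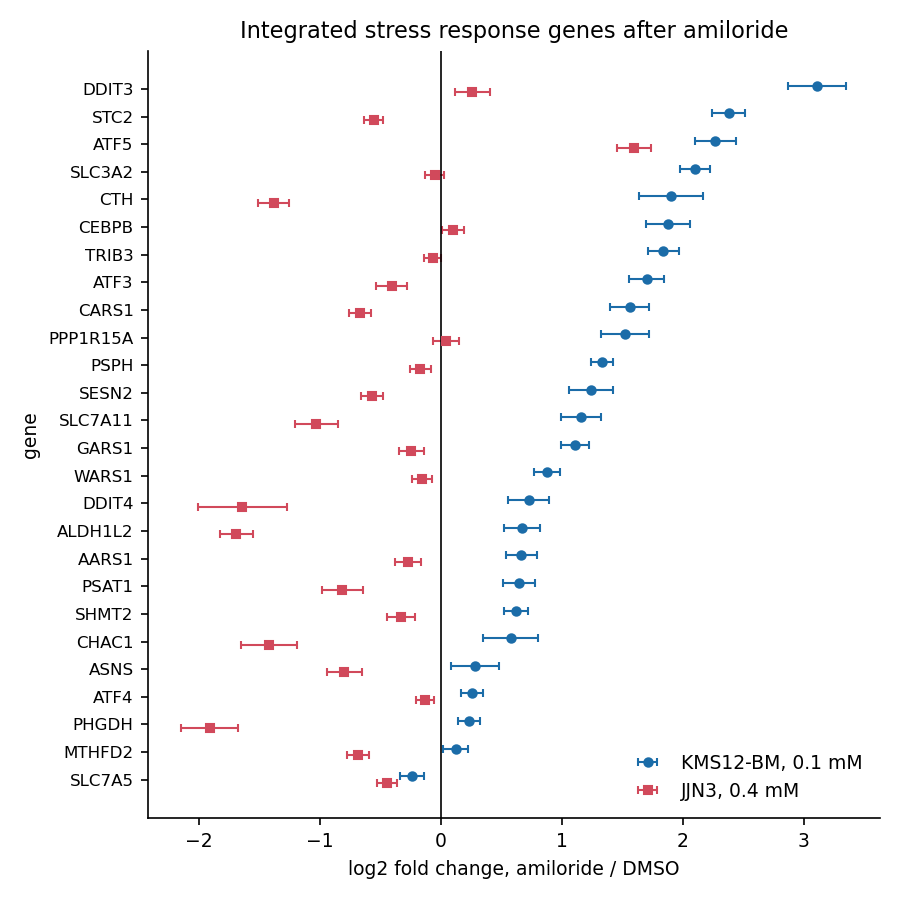
Log2 fold change of amiloride against DMSO for single genes of the ATF4 and integrated stress response list in KMS12-BM and JJN3, with points for fitted values, bars for standard errors and 3 libraries per group. STC2 lies at 2.38 and -0.55 in the 2 lines, DDIT3 at 3.11 and 0.26, and ALDH1L2 at 0.67 and -1.69.

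Other lists with lower fold changes in KMS12-BM were G1/S (0 higher and 19 lower of 37, or 20 lower adjusted over the list alone, median -0.642, camera adjusted p = 5.7e-09), cholesterol biosynthesis (2 and 15 of 24, -0.618, 2.47e-06), MYC targets and nucleolar genes (1 and 23 of 38, -0.429, 9.05e-05), the proteasome (1 and 16 of 36, or 18 lower adjusted over the list alone, -0.433, 0.00201), NRF2 (2 and 13 of 25, or 14 lower adjusted over the list alone, -0.372, 0.00489) and ion and volume homeostasis (4 and 13 of 27, or 14 lower adjusted over the list alone, -0.501, 0.0338). With an estimated correlation these adjusted p were 0.314, 0.179, 0.243, 0.396, 0.314 and 0.343. The ion and volume call was lost without KMS12BM_AMIL replicate 1 (-0.484) or JJN3_DMSO replicate 1 (-0.481). In genes without a near copy it was lost (-0.492, adjusted p = 0.087), as was NRF2 (-0.397, 0.0797), and MYC targets were lost with the exon-length trend removed as well (-0.325, 0.0628).

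Higher fold changes in KMS12-BM were found for G2/M and mitosis (26 higher and 2 lower of 38, or 29 higher adjusted over the list alone, median 0.525, camera adjusted p = 3.89e-05), NF-kappaB targets (12 and 3 of 22, 0.986, 4.63e-05), histones (8 and 1 of 13, 1.57, 0.000246), apoptosis regulators (12 and 6 of 31, or 16 and 7 adjusted over the list alone, 0.38, 0.00512), myeloma oncogenes (14 and 4 of 27, or 14 and 5 adjusted over the list alone, 0.352, 0.00763) and SR protein kinases (5 and 1 of 11, or 6 higher adjusted over the list alone, 0.246, 0.0314). With an estimated correlation the adjusted p were 0.549, 0.179, 0.322, 0.243, 0.243 and 0.343. The kinase call was lost without JJN3_DMSO replicate 3 (0.197) or JJN3_AMIL replicate 1 (0.236), in genes without a near copy (0.624, adjusted p = 0.0723), with limma voom and on ranks, and that for myeloma oncogenes on ranks.

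Genes at the ends of this contrast were ZNF512B (4.64 ± 0.15), TP73 (4.73 ± 0.74), TMEM37 (-5.95 ± 0.46), SLA2 (-4.75 ± 1.47) and DISP2 (-4.66 ± 0.28). GPAT3 (9.18 ± 0.73), HSPA12A (5.69 ± 1.02), CTSO (4.31 ± 1.53) and SPI1 (-5.11 ± 1.70) had a group at 0, so their fitted values are no bounds. MYC fell further in KMS12-BM (-0.46 ± 0.15). IRF4 (0.97 ± 0.14), XBP1 (1.09 ± 0.14), PRDM1 (0.51 ± 0.16), BCL2L11 (1.37 ± 0.12), BBC3 (2.49 ± 0.29), ATF3 (2.09 ± 0.20), CLK1 (1.37 ± 0.22), CLK4 (1.37 ± 0.21), CDKN1A (1.10 ± 0.36, under 1 CPM there), MDM2 (0.63 ± 0.12) and MCL1 (0.38 ± 0.12) had higher fold changes in KMS12-BM, and CYP1A1 (-3.05 ± 0.21) a lower one. SF3B1 (0.24 ± 0.12, adjusted p = 0.124), CLK2 (-0.12 ± 0.14, 0.547), SRSF1 (0.04 ± 0.11, 0.855), PMAIP1 (0.185), SCNN1A (0.0712), CCND1 (0.296) and MAF (0.849) were not called. Calls were lost for SLA2 without JJN3_AMIL replicate 2 (-4.27), SPI1 without JJN3_DMSO replicate 2 (-5.11), MYC without KMS12BM_AMIL replicate 3 (-0.335), CDKN1A without KMS12BM_DMSO replicate 1 (0.8875) and CTSO without KMS12BM_DMSO replicate 2 (4.29) or 3 (4.27) or KMS12BM_AMIL replicate 1 (0.545). PRDM1 was at 0.324 without JJN3_AMIL replicate 3, and SF3B1 without KMS12BM_AMIL replicate 1 (0.346) and SCNN1A without KMS12BM_AMIL replicate 2 (-7.05, no bound, since JJN3_DMSO was at 0) were called. The interaction called 7681 of 17772 genes, 3835 higher and 3846 lower in KMS12-BM. It followed GC content as well (rho -0.329 across genes, medians of 0.346 up to 42.4% GC and -0.443 from 58.1%), and with the GC trend removed the SR protein kinase list was lost (median 0.12, adjusted p = 0.101).

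TG003 was compared with DMSO in each line, with CLK activity not measured. Of 1551 processed pseudogenes tested in KMS12-BM 1402 were lower and 40 higher, and of 1471 in JJN3 1360 were lower and 36 higher. The pseudogenes RPL34P18, RPL24P8 and RPL5P23 had a count of 0 in KMS12-BM with TG003 and were at least 4409-fold, 3791-fold and 3020-fold lower than with DMSO, and RPS15AP24 and PAICSP4 at least 3021-fold and 2399-fold. In JJN3 GAPDHP65, NDUFA4P1, RPL5P23, RPL37P23 and TPT1P9 were at least 4231-fold, 3156-fold, 2929-fold, 2471-fold and 2388-fold lower. The largest rises were mostly in genes with such copies. RPS27 was at 7.83 ± 0.33 and 7.42 ± 0.09 in KMS12-BM and JJN3, RPL21 at 7.39 ± 0.16 and 6.95 ± 0.11, RPL7 at 5.94 ± 0.13 and 6.07 ± 0.13, and the glycine cleavage gene GCSH at 6.07 ± 0.14 and 5.74 ± 0.19. WASH4P (5.18 ± 0.17), itself a pseudogene, in KMS12-BM and RPL9 (5.82 ± 0.10) in JJN3 completed the 5 largest. Over 913 and 907 families of a parent gene and its pseudogenes, the SD of the log2 fold change was 0.979 and 0.909 for the parents alone and 0.607 and 0.561 for the summed family.

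**Figure D4:**
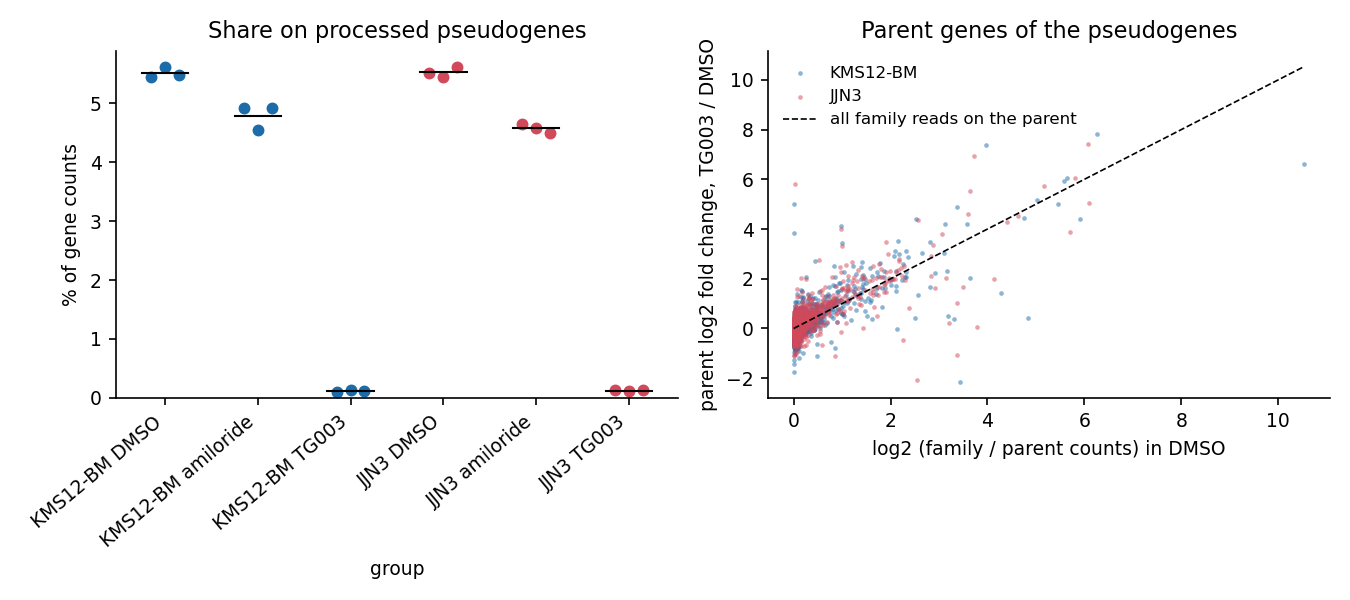
Left, percentage of gene counts on processed pseudogenes, with 1 point per library and a line at the mean of each group of 3. Right, log2 fold change of TG003 against DMSO for parent genes (vertical axis) against the log2 of family over parent counts with DMSO (horizontal axis), with 1 point per gene and a dashed line where all reads of the family would lie on the parent. The change of the parent rises with the share of its family's reads on pseudogenes (Spearman's rho 0.663 in KMS12-BM and 0.644 in JJN3, across genes).

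Lists with many copies took part in this. Ribosomal proteins were higher in 53 of 69 in KMS12-BM (2 lower, median 1.20, camera adjusted p = 1.44e-28, adjusted p = 0.426 with estimated correlation; 3 lower adjusted over the list alone) and in 50 of 69 in JJN3 (8 lower, 0.966, 3.82e-29, adjusted p = 0.133 with estimated correlation). RPS28 was at 5.02 ± 0.12 in KMS12-BM. With pseudogene counts summed into the parents, RPS28 was at -0.43 in KMS12-BM, a reversal. In JJN3 the core spliceosome (31 higher and 3 lower of 50, median 0.33, camera adjusted p = 0.00177, adjusted p = 0.903 with estimated correlation), cholesterol biosynthesis (1 and 19 of 24, -0.626, 0.0165, adjusted p = 0.203 with estimated correlation) and DNA repair (19 and 3 of 37, 0.249, 0.026, adjusted p = 0.903 with estimated correlation) were called too. The DNA repair call was lost without JJN3_DMSO replicate 3 (0.237). With the library-number set as a block, MYC targets, hypoxia and the proteasome were called as well in JJN3, and plasma cell identity in KMS12-BM.

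Coding genes without a near copy, a choice made after the pseudogenes were seen, gave the lists below for TG003. Over all tested genes the main test called none of these lists in KMS12-BM. Adjusted p was 0.101 for plasma cell identity and DNA repair, 0.159 for histones, 0.212 for ER chaperones and 0.344 to 0.818 for the others. In JJN3 the same held for hypoxia (0.0545), histones (0.0908), SR protein kinases (0.1), plasma cell identity (0.121), immediate-early genes (0.241) and ER chaperones (0.62). Limma voom, ranks and no filter called 8, 9 and 12 lists in KMS12-BM, against 1 in the main test. In JJN3 they called 15, 13 and 17, against 4. Plasma cell identity (-0.995) and histones (1.11) were called in KMS12-BM without TG003 replicate 3, and in JJN3 hypoxia without DMSO replicate 1 (-0.787) or TG003 replicate 3 (-0.732) and histones without TG003 replicate 2 (1.17). Without near copies plasma cell identity genes fell, in 18 of 25 in KMS12-BM (1 higher, median -0.913, camera adjusted p = 1.52e-09, 0.0177 with estimated correlation) and in 17 of 24 in JJN3 (1 higher, -0.608, 3.3e-06, adjusted p = 0.208 with estimated correlation; 2 higher adjusted over the list alone). IRF4, the plasma cell transcription factor, changed by -1.32 ± 0.07 in KMS12-BM and -1.05 ± 0.12 in JJN3, the surface marker gene SDC1 (CD138) by -2.13 ± 0.15 and -0.86 ± 0.08, PRDM1 by -1.01 ± 0.07 and -0.52 ± 0.14, and XBP1 by -1.11 ± 0.10 and -0.42 ± 0.09. ER chaperones fell in 15 of 22 in KMS12-BM (1 higher, median -0.696, camera adjusted p = 2.7e-06, 0.0177 with estimated correlation) and 14 of 22 in JJN3 (2 higher, -0.441, 0.00164, adjusted p = 0.208 with estimated correlation).

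SR protein kinases without a near copy rose, in 5 of 8 in KMS12-BM (2 lower, median 0.838, camera adjusted p = 0.0129, adjusted p = 0.167 with estimated correlation) and 5 of 8 in JJN3 (1 lower, 0.639, 0.00348, adjusted p = 0.419 with estimated correlation). Over all 11 tested the medians were 0.108 (5 higher, 4 lower) and 0.23 (6 and 1), not called. CLK1 rose by 1.89 ± 0.15 and 1.99 ± 0.14, CLK2 by 0.73 ± 0.09 and 1.25 ± 0.11, and CLK4 by 1.82 ± 0.16 and 1.25 ± 0.12. SRSF1 was at -0.55 ± 0.06 and -0.23 ± 0.09, and with the exon-length trend removed it was at 0.03 in JJN3, which turned its direction. SF3B1 went apart, at -0.27 ± 0.10 and 0.21 ± 0.07. Its call in KMS12-BM was lost without DMSO replicate 2 or 3 or any 1 TG003 replicate (-0.2873 to -0.2421), and in JJN3 without DMSO replicate 3 (0.174) or TG003 replicate 2 (0.189). That of SRSF1 in JJN3 was lost without DMSO replicate 1 or 2 or any 1 TG003 replicate (-0.242 to -0.195). Histones rose in 4 of 5 and 5 of 7 (medians 1.08 and 1.29, camera adjusted p = 0.0182 and 0.00968, adjusted p = 0.443 and 0.419 with estimated correlation). DNA repair genes rose in 12 and 16 of 27 (4 and 2 lower, medians 0.249 and 0.256, camera adjusted p = 0.0138 and 0.00164, adjusted p = 0.363 and 0.583 with estimated correlation; 13 higher in KMS12-BM adjusted over the list alone).

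Immediate-early genes fell in 17 of 27 and 21 of 29 (2 and 0 higher, medians -0.884 and -0.708, camera adjusted p = 0.000129 and 1.87e-05, adjusted p = 0.155 and 0.419 with estimated correlation). Hypoxia and glycolysis genes fell in 11 of 17 and 16 of 19 (0 higher in both, medians -0.518 and -0.892, camera adjusted p = 0.00233 and 1.13e-08, adjusted p = 0.167 and 0.208 with estimated correlation; 13 lower in KMS12-BM adjusted over the list alone), and cholesterol genes in 12 and 14 of 18 (0 and 1 higher, medians -0.446 and -0.602, camera adjusted p = 0.0129 and 5.53e-08, 0.443 and 0.0208 as adjusted p with estimated correlation). Called in KMS12-BM alone were MYC targets and nucleolar genes (1 higher and 20 lower of 24, median -0.486, camera adjusted p = 2.78e-05, adjusted p = 0.155 with estimated correlation), myeloma oncogenes (3 and 11 of 18, -0.322, 0.00502, adjusted p = 0.155 with estimated correlation) and apoptosis regulators (3 and 10 of 24, or 3 and 11 adjusted over the list alone, -0.152, 0.0448, adjusted p = 0.345 with estimated correlation). In JJN3 alone it was the core spliceosome (17 and 2 of 32, 0.268, 0.00304, adjusted p = 0.419 with estimated correlation). In the same genes the interaction called a difference between the lines for MYC targets (adjusted p = 1.13e-14, 0.0222 with estimated correlation) and the core spliceosome (0.00528, 0.459 with estimated correlation), but not for myeloma oncogenes (0.307) or apoptosis regulators (0.735). With the exon-length trend removed as well, 12 lists were called in KMS12-BM and 10 in JJN3, and 10 of them were shared in the same direction. G2/M (medians -0.42 and -0.307, adjusted p = 0.000918 and 0.00209) and lysosome (0.197 and 0.166, adjusted p = 0.0429 and 0.0369) were gained, while apoptosis regulators in KMS12-BM (adjusted p = 0.0859) and the core spliceosome in JJN3 (median 0.133, adjusted p = 0.101) were lost.

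Among genes without a near copy, the largest changes with TG003 in KMS12-BM were in EFCAB12 (4.09 ± 0.15), NPC1L1 (2.44 ± 0.37, under 1 CPM with DMSO), liver X receptor NR1H3 (2.13 ± 0.13), thrombin receptor F2RL3 (-3.00 ± 0.25), HYAL3 (-2.81 ± 0.27), DDN (-2.81 ± 0.20) and chemokine receptor CCR2 (-2.79 ± 0.10). In JJN3 they were in NMU (2.12 ± 0.36), RARS2 (2.01 ± 0.15), DDX60L (1.93 ± 0.14), IFI30 (-2.96 ± 0.19), chemokine CCL2 (-2.41 ± 0.36), CCR2 (-2.38 ± 0.15) and AMPD1 (-2.32 ± 0.30). MYC changed by -1.01 ± 0.13 in KMS12-BM and -0.46 ± 0.07 in JJN3, and MCL1 by -0.75 ± 0.07 and -0.42 ± 0.09. ATF3 went up in KMS12-BM (0.55 ± 0.15) and down in JJN3 (-0.34 ± 0.13). DDIT3 rose in KMS12-BM (0.99 ± 0.23) and was at 0.28 ± 0.14 in JJN3 (adjusted p = 0.117). SCNN1A (-2.21 ± 0.36, to 0.259 CPM), CCND1 (-0.73 ± 0.18) and CYP1A1 (-0.46 ± 0.09) fell in KMS12-BM, and CDKN1A (-0.90 ± 0.16), MDM2 (-0.20 ± 0.07), BBC3 (-0.63 ± 0.20) and PMAIP1 (-0.42 ± 0.16) in JJN3. CDKN1A in KMS12-BM (-0.774, adjusted p = 0.059) was called without DMSO replicate 1 (-1.007) and CCND1 in JJN3 (-0.481, 0.0707) without DMSO replicate 3 (-0.604). BCL2L11 and MAF were called in neither line. In JJN3 calls were lost for ATF3 without DMSO replicate 1 or 3 or any 1 TG003 replicate (-0.3746 to -0.2668), MDM2 without DMSO replicate 2 or 3 or TG003 replicate 1 or 2 (-0.214 to -0.156), PMAIP1 without DMSO replicate 2 or 3 or TG003 replicate 1 or 3 (-0.4634 to -0.3105) and BBC3 without TG003 replicate 2 (-0.498; -0.3885 without DMSO replicate 3). DDIT3 was at 0.6326 in KMS12-BM without TG003 replicate 2 and was called in JJN3 without DMSO replicate 3 (0.3913). The mitochondrial list did not pass its test (heavy-strand medians -0.188 in KMS12-BM and -0.0373 in JJN3, 0 of 12 lower in each), but MT-RNR1 rose (0.877, adjusted p = 6.46e-05, and 0.905, 0.0126).

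TG003 against DMSO gave 9245 calls of 15765 genes in KMS12-BM (4245 higher, 5000 lower) and 9161 of 15704 in JJN3 (4120 higher, 5041 lower). Among coding genes without a near copy, 4782 of 8842 and 4927 of 9009 were called. In these genes the change followed mean exon length (Spearman's rho -0.234 and -0.298 across genes), with medians of 0.138 and 0.168 in genes with short exons and -0.148 and -0.178 in those with long exons.

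**Figure D5:**
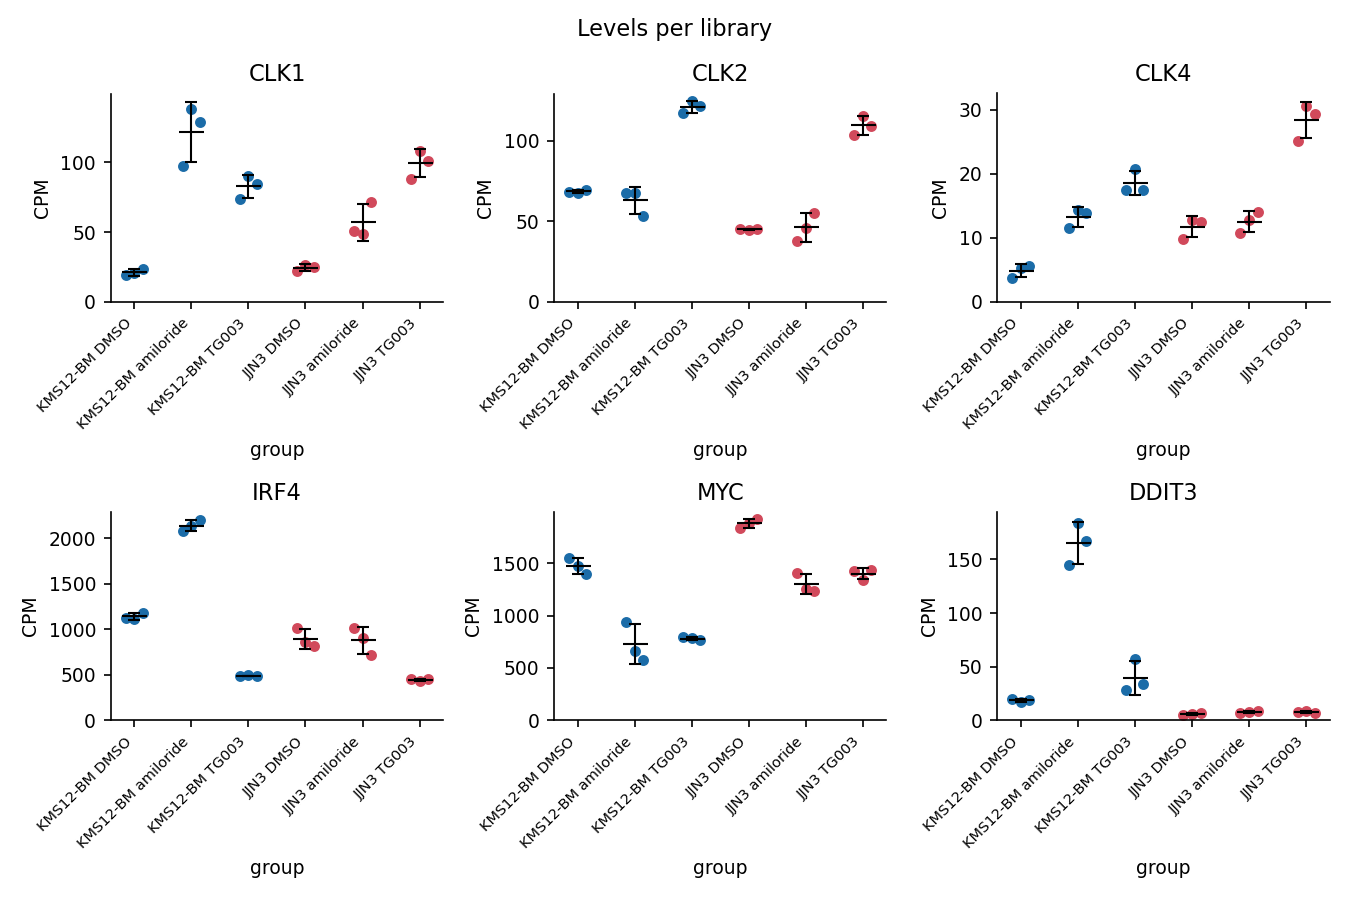
Levels of CLK1, CLK2, CLK4, IRF4, MYC and DDIT3 in unscaled CPM of the reads in genes. Points are libraries, with the mean and SD of each group of 3. In KMS12-BM the MYC libraries lay at 1399 to 1556 with DMSO, 577.8 to 938.9 with amiloride and 764 to 796.7 with TG003, and in JJN3 CLK1 lies at 24.5, 56.8 ± 13 and 99.3 ± 10.1.

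Amiloride against TG003 sets the 2 drugs side by side, which are unrelated in structure and in KMS12-BM were given at different doses, and it carries the difference in read placement named above. IRF4 was higher with amiloride by 2.17 ± 0.07 in KMS12-BM and 0.92 ± 0.12 in JJN3, and MCL1 by 1.57 ± 0.07 and 0.85 ± 0.09. CLK2 was lower with amiloride by -0.91 ± 0.09 and -1.31 ± 0.11 and CLK4 by -0.44 ± 0.15 and -1.25 ± 0.12. CLK1 was higher with amiloride in KMS12-BM (0.60 ± 0.14) and lower in JJN3 (-0.87 ± 0.13). SRSF1 (0.65 ± 0.06 and 0.28 ± 0.09) and SF3B1 (0.96 ± 0.10 and 0.24 ± 0.07) were higher with amiloride in both lines. MYC was at -0.07 ± 0.13 (adjusted p = 0.63) and -0.18 ± 0.07 (adjusted p = 0.0543). DDIT3 was at 2.12 ± 0.23 in KMS12-BM and -0.02 ± 0.14 in JJN3 (adjusted p = 0.934), and CYP1A1 at -0.77 ± 0.09 and 2.21 ± 0.21. The CLK4 call was lost without KMS12BM_AMIL replicate 1 (-0.3227) or KMS12BM_TG003 replicate 2 (-0.359) and that of SRSF1 without JJN3_AMIL replicate 1 (0.2315). MYC was called without KMS12BM_AMIL replicate 1 (-0.263) and without JJN3_AMIL replicate 1 (-0.2417).

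Lists lower with amiloride than with TG003 in KMS12-BM were ribosomal proteins (0 higher and 59 lower of 69, median -1.42, camera adjusted p = 5.87e-23), G1/S (1 and 35 of 37, -1.09, 6.93e-10), mitochondrially encoded genes (3 and 12 of 15, -4.54, 3.15e-07), cholesterol biosynthesis (1 and 20 of 24, -0.675, 0.000625), DNA repair (7 and 24 of 37, -0.404, 0.00155) and NRF2 (2 and 16 of 24, -0.494, 0.023). Higher were apoptosis regulators (23 and 2 of 29, 0.634, 0.0118), ATF4 and integrated stress response genes (22 and 1 of 26, 0.934, 0.0295) and immediate-early genes (20 and 2 of 28, 1.08, 0.0472). With an estimated correlation, in the order given, the adjusted p were 0.434, 0.434, 0.458, 0.458, 0.458, 0.434, 0.458, 0.65 and 0.53. In JJN3 the lower lists were ribosomal proteins (1 and 54 of 69, -1.36, 1.51e-38), DNA repair (3 and 26 of 37, -0.466, 0.000447), mitochondrially encoded genes (1 and 12 of 15, -1.76, 0.000815), G1/S (1 and 27 of 37, -0.524, 0.00105) and ATF4 genes (4 and 19 of 27, -0.481, 0.0314), with adjusted p = 0.0784, 0.899, 0.899, 0.899 and 0.899 with estimated correlation. Calls were lost for immediate-early genes without KMS12BM_AMIL replicate 1 (1.04) or 2 (1.10) and for ATF4 genes without JJN3_AMIL replicate 1 (-0.458) or JJN3_TG003 replicate 1 (-0.452). In KMS12-BM ATF4 genes were lost with a filter of 1 CPM, and NRF2 in genes without a near copy with the exon-length trend removed (-0.286, adjusted p = 0.102).

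In genes without a near copy, lists gained as higher with amiloride than with TG003 in KMS12-BM were SR proteins (median 0.702, adjusted p = 0.00135), hnRNP proteins (0.416, 0.0364), G2/M (0.609, 0.0364), histones (2.6, 0.00761), myeloma oncogenes (0.962, 0.000117) and NF-kappaB targets (1.36, 0.00131). In JJN3 they were immediate-early genes (21 of 29 higher, 0 lower, 0.708, 9.53e-06), plasma cell identity (0.266, 0.0381), heat shock proteins (0.37, 0.0381) and aryl hydrocarbon receptor targets (0.79, 0.0366), and hypoxia genes were lower (-0.282, 0.0381). With estimated correlation their adjusted p were 0.164 to 0.686. With the exon-length trend removed as well, hnRNP proteins in KMS12-BM (0.0639) and plasma cell identity (0.0755) and hypoxia (0.0644) in JJN3 were lost.

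Calls numbered 12267 of 15765 in KMS12-BM (6450 higher with amiloride, 5817 lower) and 9772 of 15704 in JJN3 (5230 and 4542), of which 6812 and 5359 were coding genes without a near copy. The largest differences were pseudogenes at 0 with TG003, such as RPL24P8 in KMS12-BM (at least 4389-fold higher with amiloride) and NDUFA4P1 in JJN3 (at least 2941-fold), and their parents, such as RPL21 (-8.07 ± 0.16) and RPS27 (-7.70 ± 0.33) in KMS12-BM. Without near copies they were GPRIN1 (-5.11 ± 0.28), CENPM (-4.80 ± 0.24), NPC1L1 (4.66 ± 0.23), ZNF512B (4.66 ± 0.16) and GIMAP8 (4.46 ± 0.19) in KMS12-BM, and CCR2 (3.47 ± 0.15), CCL2 (2.89 ± 0.36) and DGAT1 (-2.58 ± 0.11) in JJN3.

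The difference between the lines in the response to TG003 compares TG003 libraries with each other as well as DMSO libraries, at the same dose. MYC targets and nucleolar genes had lower fold changes in KMS12-BM, with 23 of 38 lower and 1 higher (median -0.55, camera adjusted p = 2.94e-21, a call that held with estimated correlation), or 29 lower adjusted over the list alone. WDR43 was at -0.95 ± 0.10 and MYC at -0.53 ± 0.15. Cholesterol biosynthesis genes fell less in KMS12-BM (13 higher and 1 lower of 24, or 14 and 2 adjusted over the list alone, median 0.464, camera adjusted p = 5.08e-05, adjusted p = 0.22 with estimated correlation), but in genes without a near copy this was lost (0.225, adjusted p = 0.056), and with the exon-length trend removed as well it was called (0.286, 0.032). HMGCS1 was at 1.07 ± 0.21. Ribosomal proteins were higher in 11 of 69 and lower in 1 (median 0.201, camera adjusted p = 8.24e-05, adjusted p = 0.498 with estimated correlation; 15 higher adjusted over the list alone).

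Lower in KMS12-BM were hnRNP proteins (0 higher and 9 lower of 25, or 11 lower adjusted over the list alone, median -0.235, camera adjusted p = 7.75e-06, adjusted p = 0.22 with estimated correlation), the proteasome (0 and 6 of 36, -0.227, 0.000144, adjusted p = 0.486 with estimated correlation), the core spliceosome (1 and 9 of 50, -0.156, 0.0025, adjusted p = 0.498 with estimated correlation), SR proteins (0 and 6 of 23, or 9 lower adjusted over the list alone, -0.17, 0.0025, adjusted p = 0.498 with estimated correlation) and ER chaperones (1 and 6 of 30, -0.13, 0.0128, adjusted p = 0.188 with estimated correlation; lost in genes without a near copy, -0.205, adjusted p = 0.0652). CLK2 (-0.50 ± 0.14), SF3B1 (-0.45 ± 0.12) and XBP1 (-0.67 ± 0.14) were lower and ATF3 (0.91 ± 0.20) higher in KMS12-BM. CLK1 (-0.07 ± 0.22, adjusted p = 0.945), CLK4 (0.60 ± 0.21, 0.0648), IRF4 (-0.25 ± 0.14, 0.291), PRDM1 (0.0675), SRSF1 (0.0683) and DDIT3 (0.13) were not called. Among the largest differences were pseudogenes with residual reads in 1 line (LDHAP4 7.92 ± 0.37, PTENP1 5.45 ± 0.28, EIF3FP3 4.95 ± 0.29, RPSAP15 -4.21 ± 0.24), EIF2S3B (-4.16 ± 0.31), NUTM2A-AS1 (6.53 ± 0.55), ZNF347 (-3.60 ± 0.59), the kinase gene BTK (-2.81 ± 0.40) and F2RL3 (-2.59 ± 0.25). ZNF534 (5.48 ± 1.24), SEPTIN14 (-5.70 ± 1.24) and NRIP1 (-4.21 ± 1.15) had a group at 0, so that their fitted values are no bounds. Calls were lost for CLK2 without KMS12BM_TG003 replicate 1 (-0.4622) or JJN3_TG003 replicate 2 (-0.4595), ZNF534 without JJN3_DMSO replicate 2 (4.55) and NRIP1 without KMS12BM_DMSO replicate 2 (-3.09) or any 1 KMS12BM_TG003 replicate (-4.22 to -4.19). They were gained for CLK4 without KMS12BM_DMSO replicate 3 (0.7075) or JJN3_DMSO replicate 1 (0.7072) and DDIT3 without KMS12BM_TG003 replicate 1 (0.946). The interaction called 2476 of 17772 genes (1267 higher, 1209 lower), and 1586 of the 9871 coding genes without a near copy.

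Agreement between responses was measured across genes, which are not independent replicates. For amiloride in the 2 lines Pearson's r was 0.498 and Spearman's rho 0.479 over 13913 genes. Of these, 1827 were higher in both (955.7 if independent), 2166 lower (1181) and 747 opposite (2130). For TG003 r was 0.967 and rho 0.762, and over coding genes without a near copy r was 0.71, with 1298 higher in both (554.3), 1337 lower in both (636.7) and 183 opposite (1188). Between the drugs r was 0.0902 in KMS12-BM and 0.196 in JJN3 (rho 0.195 and 0.294), and 0.317 and 0.293 without near copies. In KMS12-BM 1776 genes were higher with both drugs (1422 if independent), 2017 lower (1761) and 2380 opposite (3170). In JJN3 they were 1265 (811.2), 1719 (1204) and 1212 (1976). Both responses of a line share its 3 DMSO libraries. In 20 simulated draws without any drug effect the shared controls alone gave an r of 0.495 and 0.516 but a covariance of 0.0242 and 0.0216, against observed covariances of 0.306 and 0.308 (0.306 and 0.106 without near copies, where draws gave 0.0167 and 0.015), and at most 0 and 1 genes called in the same direction. The 3 controls of a line were too few to be divided between the drugs, so part of the excess over independence can come from them.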

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

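The scalings, the leaving out of libraries and the difference between the lines were planned. The other tests weighed in this part and the GC alternative were chosen after the results were seen.

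Results of single comparisons are set out first by what drew attention to them, which for all but 2 was a tested difference between KMS12-BM and JJN3 in the response to the same drug. For amiloride, 7681 genes passed the interaction test. Lists with a higher fold change in KMS12-BM had median log2 differences of 1.72 (ATF4 and integrated stress response), 1.57 (histones), 0.986 (NF-kappaB targets), 0.525 (G2/M and mitosis), 0.38 (apoptosis regulators), 0.352 (myeloma oncogenes) and 0.246 (SR protein kinases). Lists with a lower one had -2.95 (mitochondrially encoded genes), -0.642 (G1/S), -0.618 (cholesterol biosynthesis), -0.501 (ion and volume homeostasis), -0.433 (proteasome), -0.429 (MYC targets and nucleolar genes) and -0.372 (NRF2). With an estimated correlation 0 of these lists were called. Single genes were GPAT3 (9.18), HSPA12A (5.69), TP73 (4.73), ZNF512B (4.64), CTSO (4.31), TMEM37 (-5.95), SPI1 (-5.11), SLA2 (-4.75), DISP2 (-4.66) and MT-ND3 (-4.63) among the largest. Of the genes named throughout they included MYC (-0.457), IRF4 (0.973), PRDM1 (0.509), XBP1 (1.09), CDKN1A (1.1), MDM2 (0.63), DDIT3 (2.84), ATF3 (2.09), MCL1 (0.38), BCL2L11 (1.37), BBC3 (2.49), CLK1 (1.37), CLK4 (1.37) and CYP1A1 (-3.05). Dose was 0.1 mM in 1 line and 0.4 mM in the other, so none of these separates line from dose. GPAT3, HSPA12A, CTSO and SPI1 had a group at 0 (no bounds), and CDKN1A was under 1 CPM in KMS12-BM.

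For TG003, given at 1 dose, 2476 genes passed the same test. Lists differed by -0.55 (MYC targets and nucleolar genes), -0.235 (hnRNP proteins), -0.227 (proteasome), -0.17 (SR proteins), -0.156 (core spliceosome), -0.13 (ER chaperones), 0.464 (cholesterol biosynthesis) and 0.201 (ribosomal proteins), and only 1 of them was called with an estimated correlation, MYC targets. In genes without a near copy ER chaperones (-0.205, adjusted p = 0.0652) and cholesterol biosynthesis (0.225, 0.056) were not called. Single genes were LDHAP4 (7.92), NUTM2A-AS1 (6.53), ZNF534 (5.48), PTENP1 (5.45), EIF3FP3 (4.95), SEPTIN14 (-5.7), RPSAP15 (-4.21), NRIP1 (-4.21), EIF2S3B (-4.16) and ZNF347 (-3.6), of which ZNF534, SEPTIN14 and NRIP1 had a group at 0. MYC (-0.531), XBP1 (-0.669), ATF3 (0.914), SF3B1 (-0.45) and CLK2 (-0.497) differed among the genes named throughout. In data outside the gene counts, reads assigned to more than 1 gene made up 2.509% ± 0.0398 (SD, n = 3) with TG003 against 1.753% with DMSO in KMS12-BM, and 2.754% ± 0.0931 against 2.301% in JJN3.

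Chance cannot be excluded by other splits of the libraries for any of these counts. In the pairwise comparisons 3 against 3 libraries make 10 splits, too few for a share under 0.05. The real split gave the highest count, 1 of 10, in each: 10835 against at most 1 for amiloride and 9245 against at most 0 for TG003 in KMS12-BM, 12267 against at most 0 between the drugs there, and in JJN3 6842 against at most 2, 9161 against at most 0 and 9772 against at most 0. For the interactions, 6 of 100 splits gave as many calls for amiloride (7681, highest other 10322) and 12 of 100 for TG003 (2476, highest other 10411). The 5 and 11 other splits that did so all kept the real groups of drug and DMSO in 1 of the lines, so they carried the whole response of that line, which is a structure of the samples. The 75 splits that kept the real groups in neither line gave at most 1 and 0 calls.

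Processed pseudogenes were near 0 and their parent genes higher in all TG003 libraries of both lines. Against a fall of the pseudogenes' RNA stands the sum of each family: where pseudogenes held at least as many reads as the parent with DMSO (98 and 103 families), the parent alone had medians of 1.89 and 1.91, but the sum only 0.0994 and 0.0751. Shared reads placed differently in the TG003 libraries may account for it. A parent's rise followed the share of reads on its pseudogenes (Spearman's rho 0.663 and 0.644 across genes, against -0.0354 and -0.0962 for amiloride). Of 611 pseudogenes with at least 5 CPM with DMSO, 129 had 0 reads in all 6 TG003 libraries and 0 of them in the amiloride libraries. What made the placement differ stays open, as all and only TG003 libraries had it. Genes without a near copy may be touched: their change followed exon length with TG003, less with amiloride (rho 0.0778 and 0.061).

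With amiloride the 12 heavy-strand mitochondrial messengers fell in both lines. The tables argue against scaling or a few abundant genes as the whole cause, since over 3 other scalings the highest median of the list in either line was -1.77, and against GC content, since with that trend removed the median nearest 0 was -1.8. A loss of mitochondria or of their DNA cannot be judged from MT-RNR1, MT-RNR2 and MT-ND6 (lowest value 0.154), whose poly(A) capture may vary. A loss of poly(A) tails, so that messengers escape capture, might also give a fall, and it cannot be told apart from a fall of the RNA, because all libraries were poly(A)-selected and the rise of MT-RNR1 by 1.55 in KMS12-BM can go with either and was seen with TG003 too (0.877). A change in transcription or decay of the heavy-strand messengers was not tested and stays open as well.

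With amiloride 23 of 26 ATF4 and integrated stress response genes were higher in KMS12-BM (0 lower) and 16 of 27 lower in JJN3 (1 higher). With an estimated correlation the list was not called (adjusted p of 0.304 and 0.346, and 0.153 for the difference). The tables argue against scaling (the lowest median difference over 3 other scalings was 1.69), against a single library (1.64 at the lowest with each of 12 libraries left out in turn) and against GC content (1.82 with the trend removed). The dose of amiloride cannot be told apart from the line, since the number of lines given both doses was 0. A difference between the lines that is independent of dose may therefore exist but was not tested.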

How the results depend on the processing

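The alternatives on near copies, exon length, GC content and summed pseudogenes were chosen after seeing the data, and the others were planned. Of 523 values of named genes, 523 kept their side of the threshold with median-of-ratios scaling and 520 with upper-quartile scaling. The numbers were 514 without a filter, 516 with DESeq2 and 518 with limma voom. So did 513 of 513 without the 10 most abundant genes and 512 of 512 with 1 CPM. None turned direction under these. Upper-quartile scaling moved the median of all genes between amiloride and TG003 in KMS12-BM from 0.0425 to -0.104, and changes there are relative to it. Over the alternatives chosen in advance, calls ranged from 9765 to 11297 (amiloride, KMS12-BM), 8166 to 9874 (TG003, KMS12-BM), 10811 to 13310 (between the drugs, KMS12-BM), 6227 to 7425, 8261 to 9950 and 8769 to 10770 in JJN3, and 7209 to 8257 and 2489 to 3133 for the interactions with amiloride and TG003. With each library left out in turn they were 10163 to 10957, 8133 to 8825, 11702 to 12437, 5665 to 6346, 8241 to 8659, 8918 to 9514, 7073 to 8021 and 1842 to 2330 in the same order, list calls 70 to 78, and the correlations 0.468 to 0.495, 0.964 to 0.967, 0.0724 to 0.113 and 0.182 to 0.212. As a replicate block, the library-number set gave 11195, 9874 and 12556 calls in KMS12-BM and 7425, 9598 and 10188 in JJN3, in that order, and list calls for TG003 in JJN3 went from 4 to 7. Its residual r exceeded 0.1 in 4 of 9 library pairs per line, including the 3 of DMSO and TG003 in JJN3. In 9 and 6 the own set matched best. This argues for pairing, above all in KMS12-BM.

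Without near copies fewer genes were tested, which lowered the counts to 6724, 4768 and 6821 in KMS12-BM, 4440, 4906 and 5361 in JJN3 and 5082 for the amiloride interaction, and with the exon-length trend also removed to 6783, 4563, 6807, 4485, 4561 and 5170. List calls, 73 in the main analysis, were 118 without a filter, 182 with fry, which tests something else, and 2 with an estimated correlation. The correlations between lines for amiloride and TG003 and between drugs in KMS12-BM and JJN3 moved to 0.532, 0.976, 0.0638 and 0.177 at 10 CPM, 0.479, 0.762, 0.195 and 0.294 as rho, 0.516, 0.711, 0.312 and 0.293 without near copies, 0.515, 0.695, 0.331 and 0.32 with the exon-length trend also removed, and 0.515, 0.865, 0.206 and 0.221 with summed pseudogenes. Between drugs in KMS12-BM it was 0.109 with the GC trend removed.

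Reversed with the GC trend removed were MDM2 (-0.0399) and SRSF1 (-0.283) with amiloride in KMS12-BM. Summed pseudogenes reversed RPS28 in KMS12-BM for TG003 (-0.432) and between the drugs (0.0329), which follows from the sum. Without near copies and with the exon-length trend removed, SRSF1 with TG003 in JJN3 (0.0276), G2/M with TG003 in JJN3 (-0.307), and between the drugs MYC targets (0.447 in KMS12-BM, 0.25 in JJN3) and heat shock proteins in JJN3 (0.463) were reversed. For these lists the test direction had turned without near copies alone (-0.141, 0.443, 0.225 and 0.37 in the same order). Under fry the directions of 9 lists reversed. With TG003 these were NRF2 in KMS12-BM (-0.184) and myeloma oncogenes (-0.195), apoptosis regulators (-0.144) and markers of other cells (-0.313) in JJN3. Between the drugs they were ER chaperones (0.132) and MYC targets (0.161) in KMS12-BM, and cholesterol biosynthesis (0.0988), myeloma oncogenes (0.186) and interferon genes (0.291) in JJN3. For the other reversals the cause was not tested. With few simulated changes, edgeR recovered 38.7% and 77.6% of 1.5-fold ones in KMS12-BM and JJN3, and 18.8% in the interaction. Recovery here is not known.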

Other observations

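The gene families in this part were tested after the data had been seen. Families were taken from gene symbols, 54 in KMS12-BM and 57 in JJN3, with p adjusted over the families of a comparison. TNFRSF genes, receptors of the tumour necrosis factor family, were lower with TG003 in 11 of 17 in KMS12-BM (1 higher, median log2 -0.598, camera adjusted p = 0.0045, adjusted p = 0.357 with an estimated correlation) and in 10 of 15 in JJN3 (0 higher, -0.492, 0.0257, adjusted p = 0.294 with an estimated correlation).

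CCND1, which encodes cyclin D1, was at 969 CPM in KMS12-BM and 1.27 CPM in JJN3 with DMSO, and MAF, a transcription factor gene, at 0.377 CPM and 854 CPM. With amiloride CCND1 and MAF were not called in KMS12-BM, and MAF changed by -0.35 ± 0.12 in JJN3 (edgeR adjusted p = 0.0275).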
